A study of Arabidopsis thaliana with 24 samples.

How the data were processed

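Gene expression was measured in leaves of 3-week-old Arabidopsis thaliana plants of 4 genotypes under 2 treatments, with 3 biological replicates per combination, which gave 24 libraries in 8 groups. Per the labels, the genotypes were wild type (WT) and 3 lines in which HTA11, one of the genes for the histone variant H2A.Z, was expressed in an H2A.Z null background. In Delta28 the HTA11 protein lacked its first 28 residues, in K>R 1-9 all 9 lysines of the N-terminal tail were replaced by arginine, and in K>R 3 only the third lysine, residue 13, was replaced. Leaves were painted for 4 h either with 10 uM abscisic acid (ABA), the plant hormone of drought and salt stress, or with a mock solution of DMSO in water, both with 0.01% Silwet L-77, a wetting agent. Per the labels' protocols, RNA from about 100 mg of leaf per replicate was purified with an RNeasy kit and DNase, and 500 ng entered the Lexogen QuantSeq FWD V2 kit, which counts the 3′ ends of polyadenylated transcripts. Libraries were sequenced on a NovaSeq instrument with 150 bases from each end. Each library was assigned to its group by the genotype and treatment in its labels, and the replicate numbers are those of the labels.

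Per the submitters' processing notes, Trim Galore, STAR and RSEM were used. Their versions and settings, the genome build and the annotation are not given in the sources used here. Per the file headers, the authors' RSEM files hold for each gene an expected count, TPM, FPKM, a transcript length and an effective length. The expected counts are the authors' estimates of reads per gene before any normalisation, and between 1.21% and 2.36% of the values in a library were not whole. The deposited TPM and FPKM values are scaled by effective length, whereas reads of a 3′ end assay do not accumulate with transcript length, so they were not used for tests. The counts are of reads, and all intervals and detection floors cover counting error only.

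Each file holds 22279 genes by locus identifier, 22233 of which matched a locus of the TAIR10.1 RefSeq annotation, and 46 carry the prefix PEK_. That annotation was used for gene symbols, strand and exon number alone. As the files name no build, no coordinates are given. The deposited transcript lengths were compared with it for 11673 genes with 1 transcript. In 11593 of them (99.3%) the length equalled that of the transcript without its exon of lowest coordinate, and 0 had the full length. None of the 5293 single-exon protein-coding genes of the annotation had an entry, against 22232 of 22269 with several exons. For a minus-strand gene the missing exon is the one that holds the 3′ end, where this assay places its reads. In each library 12.6% to 17.6% (median 14.6%) of counts fell on the 11066 minus-strand genes and nearly all others on the 11173 plus-strand genes. Levels of minus-strand genes therefore rest on a minority of their reads, and single-exon genes were not analysed here.

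Expected counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the 8 groups, which left 13874 genes (8005 on the plus and 5864 on the minus strand) and at least 99.9% of the counts of each library. Library sizes were scaled by TMM, with factors from 0.886 to 1.135. A single quasi-likelihood model with a mean per group was fitted to all 24 libraries, so that all comparisons share 1 estimate of spread with 16 residual degrees of freedom. The biological coefficient of variation was 0.364. Genes were called at a Benjamini-Hochberg adjusted p below 0.05 in edgeR's quasi-likelihood test, which is two-sided. The 12 comparisons were ABA against mock within each genotype, the difference of that response between genotypes (an interaction: each mutant against WT, K>R 1-9 against Delta28, and K>R 3 against K>R 1-9), and each mutant against WT in mock leaves. Levels are given as CPM, read counts scaled by effective library size, with the SD over 3 libraries, and fold changes on the log2 scale with their standard error (SE). A fold against a group with 0 counts is a lower bound against a floor of 3 counts over the group, and with 1 to 3 counts the pooled ratio is given with its exact binomial 95% interval.

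The size of the ABA response was scored per library as the mean log2 CPM (prior count 2) over genes induced, or repressed, at least 2-fold by ABA on average over the 4 genotypes with equal weight. Responses were compared between genotypes by an exact two-sided permutation test with genotype exchanged within each treatment (400 arrangements, smallest possible p 0.005), adjusted over the 6 tests. The 23 gene lists are ABA receptors, clade A PP2C phosphatases, ABA-linked transcription factors and AFP regulators, LEA, dehydrin and other ABA marker genes, ABA metabolism and transport, osmolyte and sugar metabolism, photosystem antenna and Rubisco, auxin response and expansin growth genes, jasmonate synthesis and response, salicylate and immune response, heat shock, flowering time and floral regulators, H2A.Z genes, SWR1 and INO80 remodeller subunits, other H2A genes, circadian clock, senescence, touch, guard cell, epidermis, vascular and dividing cell markers, and reference genes. Of their 270 members 244 had an entry, 123 of these on the minus strand, and the 26 others are single-exon genes. Lists of at least 3 tested members (20 lists) were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists within a comparison, with a correlation estimated per list as an alternative. The H2A.Z genes and touch lists had 2 tested members each and the dividing cell markers 1, so camera was not run on them.

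The genes named are HTA8, HTA9 and HTA11 in every library; per comparison the 5 largest and 5 smallest log2 fold changes among called genes with a mean of at least 5 CPM and no overlap between the replicates of both groups; and up to 4 members of each list by smallest adjusted p, of which those with an informative value are given. With 3 against 3 libraries, 10% of unchanged genes separate without overlap. Groups, comparisons, tests, lists and the naming rule were fixed before the data were examined, as were these alternatives: scaling by DESeq2 size factors (RLE) in edgeR, DESeq2 1.42.0 in place of edgeR, no filter, a stricter filter (CPM of at least 5 in 3 libraries), a 2-fold minimum, the groups compared fitted alone, a replicate block, leaving out each library, and for the scores other gene sets, a prior count of 0.5 and a mean CPM of at least 10. Chosen after the data were seen were plus-strand genes alone, the joint removal of WT mock replicate 2 and K>R 3 mock replicate 2, and all alternatives for the lists except the estimated correlation.

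Total counts ranged from 1565518 (WT mock replicate 2) to 15086279 (WT ABA replicate 3), with a median of 7142427, so that a floor of 3 counts corresponded to between 0.190 and 1.69 CPM. Counts of replicates of a group differed by far more than sampling noise (chi-square per degree of freedom 11.9 to 121), so each was counted as a separate replicate. The median SE of a log2 fold change was 0.42 for ABA in WT and 0.58 for the interaction of Delta28 with WT. The pipeline was tested on simulated counts with 50 genes changed at each log2 size of 1, 2, 3 and 4. For ABA in WT it recovered 14%, 48%, 78% and 82% of them, for the interaction of Delta28 with WT 0%, 40%, 66% and 70%, and for Delta28 against WT in mock leaves 8%, 60%, 72% and 90%, each over 13874 genes. The simulated genes were drawn independently, with equal group means apart from the 200 changed genes, so recovery in the real data may be lower.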

Results

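The transcriptomes of 24 leaf samples of Arabidopsis thaliana were profiled by 3′ end RNA sequencing. They covered 4 genotypes, WT, Delta28, K>R 1-9 and K>R 3, each painted for 4 h with mock solution or 10 uM ABA, with 3 biological replicates per group. The question set by the study was whether the N-terminal tail of H2A.Z alters how strongly genes respond to ABA. H2A.Z is a histone variant that the SWR1 complex places around transcription start sites. By the labels no line carried unmodified HTA11 in the null background, so a difference from WT cannot be assigned to the tail alone. Total counts per library ranged from 1565518 to 15086279, with a median of 7142427. WT mock replicate 2 was the shallowest library and WT ABA replicate 3 the deepest, so WT held both extremes. The first principal component of log2 CPM, with 30.1% of the variance, separated ABA from mock libraries.

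The H2A.Z genes were examined first, because the labels place the mutants in an H2A.Z null background. HTA9 (AT1G52740) was expressed at 327 ± 74.8 CPM in WT mock leaves (mean ± SD, n = 3 libraries) and at 63.0 ± 4.84, 57.0 ± 2.89 and 56.7 ± 2.61 CPM in Delta28, K>R 1-9 and K>R 3 mock leaves. Over both treatments the 6 WT libraries lay between 267 and 411 CPM and the 18 mutant libraries between 53.8 and 118 CPM. HTA9 fell in every mutant in mock leaves, with log2 fold changes of -2.38, -2.52 and -2.53 (SE 0.19 each) and adjusted p of 3.13e-07, 1.14e-07 and 1.13e-07 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. These calls held without any single library. The HTA9 transcripts left in the mutants cannot check the null label, since these counts do not show whether a functional protein is made. HTA8 (AT2G38810) had 0 counts in all 24 libraries, where 3 counts would have been 0.190 to 1.69 CPM. It lies on the minus strand, so the deposited gene model lacks its 3′ exon and this 0 does not inform on its expression.

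HTA11 (AT3G54560), the gene supplied to the mutants, was at 4.71 to 9.79 CPM in WT. In Delta28 mock leaves it was at 7.97 ± 3.08 CPM. K>R 1-9 libraries held 420 to 1008 CPM, with 450 ± 37.0 CPM in mock and 681 ± 283 CPM in ABA leaves. In K>R 3 the mock replicates were at 10.9, 789 and 36.0 CPM and the ABA replicates at 20.1, 5.67 and 22.1 CPM. Mock replicate 2, with 2824 counts, thus stood apart from the other K>R 3 libraries and within the range of K>R 1-9. Against WT mock leaves HTA11 was higher in K>R 1-9 (log2 fold change 6.10, SE 1.07, adjusted p = 0.0154 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), a call lost without any 1 of the 3 WT mock replicates, with adjusted p up to 0.162. The mock libraries themselves lay far apart, at 5.12 to 7.88 CPM in WT and 420 to 491 CPM in K>R 1-9. The SE draws on the spread over all 24 libraries, which include the unlike K>R 3 mock replicates. A lost call therefore does not show that 1 WT replicate makes the difference. The log2 fold changes in K>R 3 (5.40, adjusted p = 0.0746) and Delta28 (0.27, adjusted p = 0.975) did not pass in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Mock replicate 2, at 789 CPM against 10.9 and 36.0 CPM, dominates the K>R 3 value. Reads of a 3′ end assay lie outside the altered N-terminal codons, so the HTA11 level does not check the change in the tail. Whether the supplied gene carries the 3′ end of HTA11 in each line is not given in the sources used here, so this level may leave out its transcripts.

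**Figure D1:**
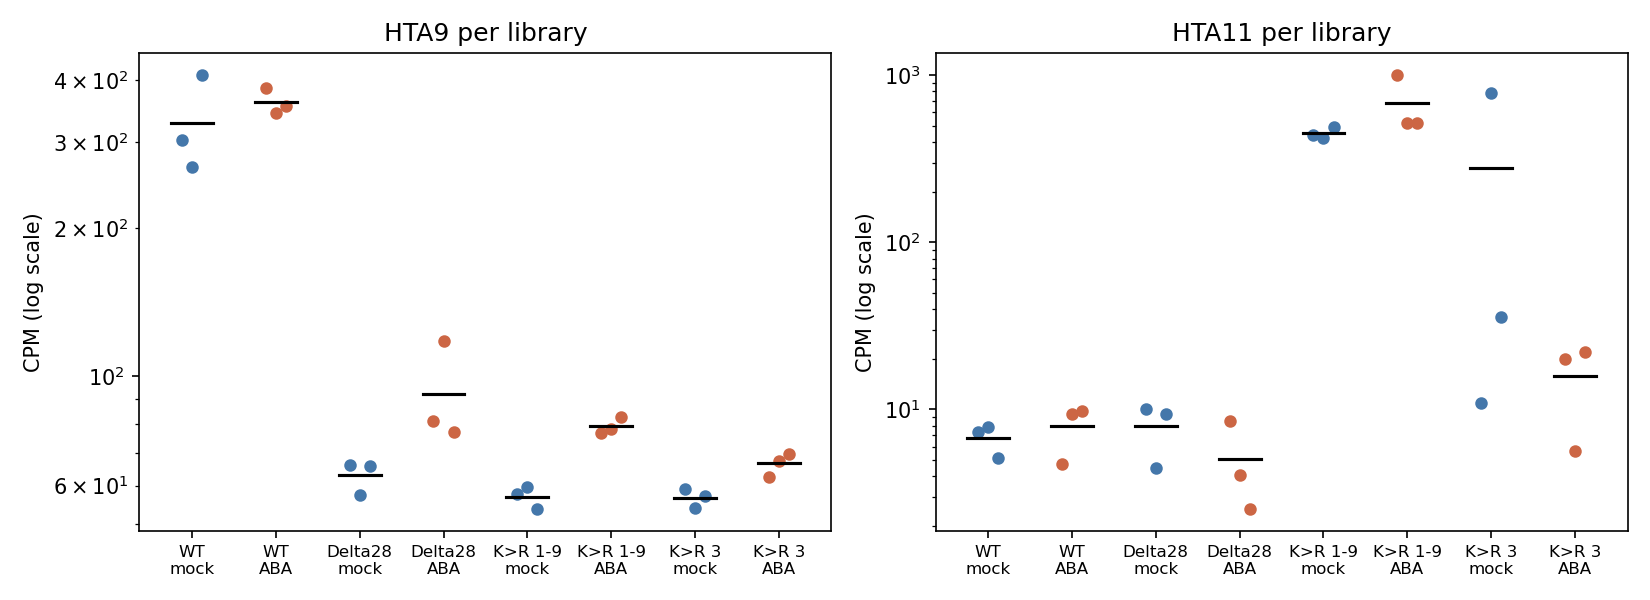
HTA9 and HTA11 levels in CPM on log axes, 1 point per library, in mock (blue) and ABA (orange) leaves of the 4 genotypes, with group means of 3 libraries as black lines. HTA9 lay at 267 to 411 CPM in WT and 53.8 to 118 CPM in the mutants, and 1 K>R 3 mock library reached 789 CPM of HTA11.

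ABA against mock in WT gave the reference response. LEA7 (AT1G52690), a late embryogenesis abundant (LEA) protein of drying tissue, went from 2 counts over the 3 mock libraries to 1247 ± 904 CPM (pooled ratio 10609, 95% interval 2937 to 87605), and the LEA family gene AT3G02480 from 3 counts to 458 ± 193 CPM (pooled ratio 2823, 95% interval 966 to 13692). HIPP22 (AT1G22990), a metal-binding isoprenylated protein, and SAG29 (AT5G13170), a sugar transporter of senescing leaves, had 0 counts in mock and were at least 194-fold and 101-fold higher with ABA, while the LEA gene AT2G42560 was at least 84.3-fold higher. The largest decreases were those of the cysteine proteinase AT2G27420 (log2 fold change -5.79, SE 1.54), PAL2 (AT3G53260), a phenylalanine ammonia-lyase (-4.43, SE 1.00), the transporter AT5G62730 (-4.38, SE 0.98), LHCB2.2 (AT2G05070), a light-harvesting protein (-4.02, SE 0.78), and the RNA-binding BTR1L (AT5G04430; -3.71, SE 0.75).

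In total 798 of 13874 genes were called in WT by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 573 higher (71.8%) and 225 lower, 651 of them by at least 2-fold. DESeq2 called 1277 genes, 779 higher (61.0%) and 498 lower. The WT count fell to 500, 263 and 375 without mock replicates 1, 2 and 3 and to 382 and 240 without ABA replicates 1 and 2. It was 809 without ABA replicate 3, and 255 without WT mock replicate 2 and K>R 3 mock replicate 2 together. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the call of AT2G42560 held in 1 of 6 leave-outs (up to adjusted p = 0.111, lost except without WT ABA replicate 3), as did that of AT2G27420 (up to 0.136, lost except without WT mock replicate 1). PAL2 and AT5G62730 were lost without ABA replicate 2 (adjusted p = 0.0667 each) and BTR1L without mock replicate 2 (adjusted p = 0.0501) in the same edgeR test.

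Of 9 clade A PP2C phosphatases, which hold the ABA-activated kinases in check, 6 rose in WT, and 8 did when adjusted over the list alone. Among them HAI1 (AT5G59220) had a log2 fold change of 5.50 (SE 1.26), HAI2 (AT1G07430) 3.37 (SE 0.74), ABI2 (AT5G57050) 2.60 (SE 0.53) and HAB2 (AT1G17550) 1.23 (SE 0.28). The list passed camera (Benjamini-Hochberg adjusted p = 7.57e-08; adjusted p = 0.114 with an estimated correlation). None of the 4 ABA receptors tested passed, with PYL7 (AT4G01026) at 0.51 and PYL8 (AT5G53160) at 0.31 (camera adjusted p = 0.84). The other receptors on the list, PYR1, PYL2, PYL4, PYL5 and PYL6, are single-exon genes without an entry, so this does not describe the whole family. Of 15 transcription factors and AFP regulators 8 rose (9 adjusted over the list alone). They included AFP1 (AT1G69260), a repressor of ABI5 action (5.19, SE 0.82), RD26 (AT4G27410), a NAC factor (4.81, SE 0.92), MYB2 (AT2G47190; 3.28, SE 0.51) and HB7 (AT2G46680; 3.09, SE 0.58). Camera gave this list an adjusted p = 1.36e-10, and adjusted p = 0.0619 with an estimated correlation. The calls of HAI2 and HAB2 were lost without mock replicate 3 or ABA replicate 2 (adjusted p up to 0.0947 and 0.0864) and that of HAI1 without any mock replicate or ABA replicate 2 (up to 0.078) in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

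Of 18 LEA, dehydrin and other ABA marker genes 13 rose in WT (16 adjusted over the list alone; camera adjusted p = 8.28e-20, and adjusted p = 0.0226 with an estimated correlation). RD29B (AT5G52300), a desiccation-responsive gene, had a log2 fold change of 7.61 (SE 1.07). KIN1 (AT5G15960), a cold- and ABA-induced gene whose reads may be split with its near-copy KIN2, went from 198 ± 58.9 to 2560 ± 264 CPM (3.69, SE 0.56), and LTP3 (AT5G59320), a lipid transfer protein with the near-copy LTP4, changed by 3.19 (SE 0.49). Among 10 genes of ABA metabolism and transport 2 rose (2 adjusted over the list alone; camera adjusted p = 0.00022, and adjusted p = 0.0376 with an estimated correlation), the ABA hydroxylases CYP707A3 (AT5G45340; 4.04, SE 0.55) and CYP707A1 (AT4G19230; 3.99, SE 0.77), which break ABA down. Of 9 genes of osmolyte and sugar metabolism 3 rose (4 adjusted over the list alone), the sucrose synthase SUS3 (AT4G02280; 4.16, SE 0.74), the beta-amylase BAM1 (AT3G23920; 2.13, SE 0.45) and GOLS2 (AT1G56600; 3.25, SE 0.73), which makes galactinol. Camera gave adjusted p = 0.00174 for this list and adjusted p = 0.0918 with an estimated correlation. The GOLS2 call was lost without mock replicate 2 or ABA replicate 2 (adjusted p up to 0.0839 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

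Of 20 photosystem antenna and Rubisco genes 3 fell in WT (9 adjusted over the list alone; camera adjusted p = 1.94e-09, and adjusted p = 0.29 with an estimated correlation): LHCB2.2, LHCB2.3 (AT3G27690; -3.22, SE 0.74), whose reads are hard to separate from those of LHCB2.2, and the Rubisco activase RCA (AT2G39730; -2.01, SE 0.41). Of 9 senescence genes 3 rose (4 adjusted over the list alone; camera adjusted p = 1.1e-06, and adjusted p = 0.0203 with an estimated correlation), SAG29, SAG13 (AT2G29350; 3.36, SE 0.68) and PAO (AT3G44880), an enzyme of chlorophyll breakdown (1.79, SE 0.33). Of 16 jasmonate genes 3 rose (6 adjusted over the list alone; camera adjusted p = 3.23e-05, and adjusted p = 0.352 with an estimated correlation), all of them JAZ repressors of jasmonate signalling: JAZ7 (AT2G34600; 5.35, SE 1.24), JAZ2 (AT1G74950; 3.52, SE 0.86) and JAZ12 (AT5G20900; 1.19, SE 0.34). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment RCA was lost without mock replicate 2 (adjusted p = 0.0513), LHCB2.3 without ABA replicate 1 or 2 (up to 0.0896), JAZ7 without mock replicate 1 or 3 (up to 0.0876) and JAZ2 without any mock replicate or ABA replicate 2 (up to 0.0792). JAZ12 was lost in 5 of 6 leave-outs (up to 0.198 in that edgeR test, kept without ABA replicate 3).

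The remaining lists did not pass camera in WT. None of 13 auxin and expansin genes (adjusted p = 0.177), 10 flowering genes (0.802), 9 SWR1 and INO80 subunits (0.699; 2 rose adjusted over the list alone), 7 other H2A genes (0.507), 3 epidermis markers (0.629) and 9 reference genes (0.84) was called. In the clock list TOC1 (AT5G61380), an evening gene, rose by 1.24 on the log2 scale (SE 0.25) and the morning genes RVE8 (AT3G09600; -1.49, SE 0.36) and PRR9 (AT2G46790; -1.38, SE 0.34) fell, with 11 others not called (camera adjusted p = 0.212). The salicylate regulator NPR1 (AT1G64280) was the 1 of 17 salicylate genes called (-1.54, SE 0.46; camera adjusted p = 0.554). The heat shock factor HSFB2A (AT5G62020) was the 1 of 8 heat shock genes (1.53, SE 0.36; 0.699, with a median of -0.41 but an upward test). The proton pump AHA3 (AT5G57350) was the 1 of 6 vascular markers (1.03, SE 0.24; 0.699). The potassium channel KAT1 (AT5G46240) was the 1 of 4 guard cell markers (1.80, SE 0.36; 0.711). Neither of the 2 touch genes, neither of the 2 H2A.Z genes and not the 1 dividing cell marker tested was called. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment TOC1 passed without any single library. RVE8 was lost without mock replicate 2 or 3 or ABA replicate 1 or 2 (adjusted p up to 0.0923), PRR9 without mock replicate 2 or 3 or ABA replicate 1 or 3 (up to 0.102) and NPR1 except without mock replicate 1 (up to 0.382) in that edgeR test. HSFB2A was lost without mock replicate 2 or ABA replicate 2 (up to 0.0945) and AHA3 without mock replicate 3 or ABA replicate 1 or 2 (up to 0.0819).

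**Figure D2:**
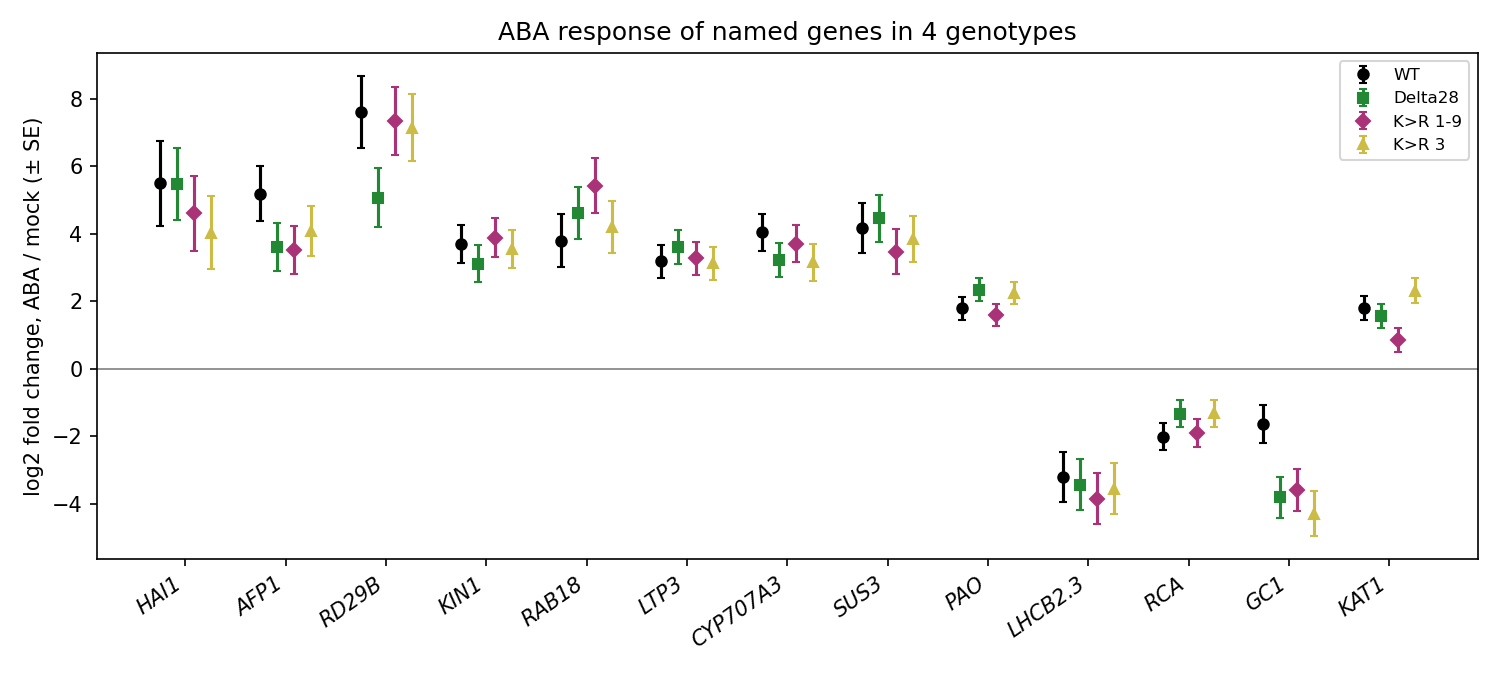
ABA against mock log2 fold change (points) with its standard error (bars) of 13 genes in the 4 genotypes, 3 against 3 libraries each. In WT the values ran from -3.22 for LHCB2.3 to 7.61 for RD29B.

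The same comparison in Delta28 gave the response of the line whose HTA11 lacks its first 28 residues. The LEA genes AT2G42560 and AT4G21020 and the carnitine transporter OCT1 (AT1G73220) had 0 counts in mock and were at least 736-fold, 301-fold and 305-fold higher with ABA. LEA7 went from 1.12 ± 0.294 to 4388 ± 3069 CPM (log2 fold change 11.88, SE 1.71) and AT3G02480 changed by 10.82 (SE 1.45). The largest decreases were those of AT2G27402, annotated as plastid transcriptionally active (-5.62, SE 0.99), AT5G62730 (-4.89, SE 1.02), AT1G11850 (-4.64, SE 1.09), the growth regulator PRE1 (AT5G39860; -4.60, SE 1.25) and GC1 (AT1G22690), a guard cell marker (-3.82, SE 0.62). In total 1977 genes were called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1206 higher and 771 lower, 1480 of them by at least 2-fold. The count was 888 without mock replicate 1, 1147 without ABA replicate 1 and 991 without ABA replicate 2. In that edgeR test with Benjamini-Hochberg adjustment AT1G11850 was lost without mock replicate 1 (adjusted p = 0.138) and PRE1 without mock replicate 1 or ABA replicate 2 (up to 0.0771).

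In Delta28 7 of 9 PP2C phosphatases rose (9 adjusted over the list alone), among them AHG1 (AT5G51760), with a pooled ratio of 143 (95% interval 48.7 to 699), and HAI1 (5.47, SE 1.07). Of 15 transcription factors and regulators 9 rose (12 adjusted over the list alone), among them the NAC factors NAP (AT1G69490; 3.92, SE 0.55) and ANAC055 (AT3G15500; 5.46, SE 1.05) and the ABA-responsive bZIP factor ABF3 (AT4G34000; 1.98, SE 0.39). Of 18 LEA and marker genes 14 rose (17 adjusted over the list alone), among them the dehydrin RAB18 (AT5G66400; 4.61, SE 0.77) and LTP4 (AT5G59310; 4.89, SE 0.81). Of 10 genes of ABA metabolism 3 rose (4 adjusted over the list alone), with CYP707A3 at 3.23 (SE 0.50). Of 9 osmolyte genes 4 rose (5 adjusted over the list alone), with SUS3 at 4.46 (SE 0.69) and the proline synthesis gene P5CS1 (AT2G39800) at 1.75 (SE 0.45). Camera gave adjusted p of 6.68e-07, 3.45e-09, 4.48e-14, 0.00424 and 0.000719 for these 5 lists, and with an estimated correlation adjusted p = 0.157 for the phosphatases and adjusted p = 0.071 for the others. The ABA metabolism call was also lost over plus-strand genes alone (adjusted p = 0.0957 by camera), an alternative chosen after the data were seen.

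Of 9 senescence genes 6 rose in Delta28 (7 adjusted over the list alone; camera adjusted p = 1e-07, and adjusted p = 0.00946 with an estimated correlation), with PAO at 2.34 (SE 0.34), SAG13 at 4.47 (SE 0.71) and the chlorophyll b reductase NYC1 (AT4G13250) at 1.49 (SE 0.41). Of 20 antenna and Rubisco genes 6 fell (11 adjusted over the list alone; camera adjusted p = 2.56e-06, and adjusted p = 0.469 with an estimated correlation). LHCB2.3 was at -3.44 (SE 0.75) and the small Rubisco subunit gene RBCS1B (AT5G38430), which has near-identical copies, at -2.89 (SE 0.64). The jasmonate list missed the threshold (camera adjusted p = 0.0518, and 0.0478 with RLE scaling), with 1 of 16 genes called, JAZ1 (AT1G19180; 1.91, SE 0.62). Of 4 guard cell markers KAT1 rose (1.57, SE 0.35) and GC1 fell (camera adjusted p = 0.418). HTA9 rose slightly (0.55, SE 0.18, adjusted p = 0.0483 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). In the same edgeR test P5CS1 was lost without mock replicate 1 or 2 (adjusted p up to 0.0698), NYC1 and JAZ1 without any mock replicate or ABA replicate 2 (up to 0.141 and 0.488) and HTA9 in 5 of 6 leave-outs (up to 0.297, kept without ABA replicate 3) and with no filter (0.0901).

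In K>R 1-9, with all 9 tail lysines replaced, AT2G42560 had 1 count over the mock libraries and DAA1 (AT1G64110), an ATPase, had 2, with pooled ratios of 703 (95% interval 126 to 27810) and 309 (95% interval 85.3 to 2557). HIPP22 changed by 8.38 (SE 0.97), RD29B by 7.35 (SE 1.00) and LEA7 by 7.29 (SE 1.39). LEA7 was at 20.6 ± 35.6 CPM in K>R 1-9 mock leaves, with an SD above the mean, so unlike mock libraries enter its fold change. Its difference in response from WT (-5.96, SE 2.38) was not called by edgeR. The extensin family gene AT3G16660 (-5.55, SE 0.94), the kinase AT1G66930 (-4.76, SE 1.12), the lipase AT1G33811 (-4.51, SE 1.05), LHCB2.3 (-3.85, SE 0.77) and AT1G11850 (-3.84, SE 1.09) fell most. In total 1292 genes were called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 796 higher and 496 lower, 1023 of them by at least 2-fold. The count was 532 without mock replicate 2 and 641, 829 and 740 without ABA replicates 1, 2 and 3. In that edgeR test with Benjamini-Hochberg adjustment AT1G11850 was lost in 5 of 6 leave-outs (adjusted p up to 0.145, kept without mock replicate 1).

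Of 18 LEA and marker genes 17 rose in K>R 1-9 (17 adjusted over the list alone; camera adjusted p = 4.02e-22, and adjusted p = 0.0252 with an estimated correlation), with KIN1 going from 229 ± 178 to 3385 ± 1297 CPM (3.88, SE 0.57) and RAB18 at 5.42 (SE 0.81). Of 9 PP2C phosphatases 6 rose (8 adjusted over the list alone; camera adjusted p = 1.68e-06, and adjusted p = 0.173 with an estimated correlation), with HAI1 at 4.60 and HAI2 at 3.28 (SE 0.71). Of 15 transcription factors and regulators 8 rose (11 adjusted over the list alone; camera adjusted p = 1.87e-07, and adjusted p = 0.126 with an estimated correlation), with AFP1 at 3.51 (SE 0.71) and NAP at 2.25 (SE 0.51). Of 10 ABA metabolism genes 2 rose (3 adjusted over the list alone; camera adjusted p = 0.000775, and adjusted p = 0.041 with an estimated correlation), with CYP707A3 at 3.71 (SE 0.54). Of 9 osmolyte genes 4 rose (4 adjusted over the list alone; camera adjusted p = 0.000347, and adjusted p = 0.041 with an estimated correlation), with P5CS1 at 2.48 (SE 0.46). The HAI1 call was lost without mock replicate 2 or 3 (adjusted p up to 0.0586 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

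Of 20 antenna and Rubisco genes 7 fell in K>R 1-9 (14 adjusted over the list alone; camera adjusted p = 1.16e-09, and adjusted p = 0.191 with an estimated correlation), with RCA at -1.91 (SE 0.41). Of 9 senescence genes 3 rose (4 adjusted over the list alone; camera adjusted p = 5.52e-05, and adjusted p = 0.0409 with an estimated correlation), with SAG29 at 3.52 (SE 0.59) and PAO at 1.59 (SE 0.33). None of 16 jasmonate genes was called, by either adjustment, with JAZ8 (AT1G30135) at 2.90 (adjusted p = 0.0901 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The list as a whole passed camera (adjusted p = 0.00877; adjusted p = 0.428 with an estimated correlation), and did not without mock replicate 3 or ABA replicate 3 (adjusted p up to 0.206). Of 4 guard cell markers GC1 (-3.59, SE 0.62) and FAMA (AT3G24140), a guard cell transcription factor (-2.00, SE 0.52), fell, while KAT1 was at 0.85 and the kinase HT1 (AT1G62400) at -0.54 (camera adjusted p = 0.0914). FAMA was lost without mock replicate 2 or 3 or ABA replicate 1 or 2 (adjusted p up to 0.0722 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

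In K>R 3, with only lysine 13 replaced, HIPP22, SAG29 and the lipid-transfer family gene AT2G37870 had 0 counts in mock and were at least 493-fold, 115-fold and 101-fold higher with ABA. AT3G02480 changed by 9.82 (SE 1.42) and LEA7 by 9.56 (SE 1.58). The methyltransferase family gene AT3G23510 (-5.03, SE 1.34), AT5G62730 (-4.79, SE 1.03), AT1G66930 (-4.45, SE 1.14), AT2G10940 (-4.34) and GC1 (-4.30, SE 0.66) fell most. In total 1496 genes were called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 844 higher and 652 lower, 1115 of them by at least 2-fold. The count was 529 without mock replicate 1, 828 without mock replicate 3 and 910 without ABA replicate 2, and 430 when the K>R 3 libraries were fitted alone. It was 1160 without ABA replicate 3, which stood apart from the 5 other K>R 3 libraries on the second principal component (31.1 against -53.9 to -32.5). HTA11 itself was lower with ABA (-4.11, SE 0.96, adjusted p = 0.00948), which rested on mock replicate 2 (adjusted p = 0.558 without it) in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In the same edgeR test AT3G23510 was lost without mock replicate 1 or ABA replicate 2 or 3 (adjusted p up to 0.115), AT1G66930 without mock replicate 2 or ABA replicate 2 (up to 0.0614) and AT2G10940 without mock replicate 1 or ABA replicate 2 (up to 0.143).

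Of 9 PP2C phosphatases 6 rose in K>R 3 (8 adjusted over the list alone), with PP2CA (AT3G11410) at 3.03 (SE 0.62) and HAB2 at 1.54 (SE 0.27). Of 15 transcription factors and regulators 6 rose (11 adjusted over the list alone), with AFP1 at 4.09 (SE 0.74) and RD26 at 3.17 (SE 0.74). Of 18 LEA and marker genes 12 rose (17 adjusted over the list alone), with RD29B at 7.15 (SE 1.00). Of 10 ABA metabolism genes 3 rose (3 adjusted over the list alone), with CYP707A3 at 3.15 (SE 0.54) and the ABA synthesis gene ABA1 (AT5G67030) at 1.01 (SE 0.32). Of 9 osmolyte genes 4 rose (adjusted over the list alone 4 rose and 2 fell), with P5CS1 at 2.46 (SE 0.46). Camera gave adjusted p of 4.23e-08, 5.85e-07, 5.12e-15, 0.00738 and 0.00544 for these 5 lists, and with an estimated correlation adjusted p = 0.0552 for the LEA and marker genes and adjusted p = 0.122 for the others. The ABA metabolism call was also lost over plus-strand genes alone (camera adjusted p = 0.0825). RD26 was lost without mock replicate 1 (adjusted p = 0.058) and ABA1 with RLE scaling (0.0505) and in 4 of 6 leave-outs (up to 0.199, kept without mock replicate 1 or ABA replicate 1) in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

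Of 20 antenna and Rubisco genes 6 fell in K>R 3 (8 adjusted over the list alone; camera adjusted p = 5.95e-07, and adjusted p = 0.368 with an estimated correlation), with LHCB2.3 at -3.56 (SE 0.76) and RBCS1B at -2.81 (SE 0.64). Of 9 senescence genes 4 rose (4 adjusted over the list alone; camera adjusted p = 9.47e-06, and adjusted p = 0.048 with an estimated correlation), with PAO at 2.24 (SE 0.34). Of 16 jasmonate genes 4 rose (5 adjusted over the list alone; camera adjusted p = 0.000143, and adjusted p = 0.368 with an estimated correlation), with the repressor JAZ9 (AT1G70700) at 1.84 (SE 0.48) and the storage protein VSP2 (AT5G24770) at 3.74 (SE 1.15). Of 6 vascular markers 2 rose (2 adjusted over the list alone; camera adjusted p = 0.0237, and adjusted p = 0.141 with an estimated correlation). They were AHA3 (1.69, SE 0.24) and the phloem sugar exporter SWEET12 (AT5G23660; 1.84, SE 0.59). The list call was lost without mock replicate 2 or ABA replicate 3 (camera adjusted p up to 0.0936). KAT1 rose (2.32, SE 0.36) and GC1 fell among 4 guard cell markers (camera adjusted p = 0.742). SWEET12 was lost with RLE scaling, with no filter and without mock replicate 1 or 2 or ABA replicate 2 or 3 (adjusted p up to 0.22), JAZ9 without mock replicate 1 or 2 or ABA replicate 3 (up to 0.105) and VSP2 in 5 of 6 leave-outs (up to 0.157, kept without ABA replicate 1) in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

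The 4 responses shared many genes and no gene was called with opposite signs in any pair of genotypes. Across genotypes 3072 genes were called at least once, of which 286 were higher and 72 lower in all 4. Of the 798 genes called in WT, 779 had the same sign of fold change in all 3 mutants. Delta28 shared 466 of the 573 genes higher in WT (81.3%), against 49.8 for independent lists, and 142 of the 225 lower (63.1%), against 12.5. K>R 1-9 shared 379 and 115 (66.1% and 51.1%), against 32.9 and 8.04, and K>R 3 shared 385 and 114 (67.2% and 50.7%), against 34.9 and 10.6. These shares grow with the number of genes that a mutant calls. Of the genes higher in Delta28, K>R 1-9 and K>R 3, 38.6%, 47.6% and 45.6% were also higher in WT. For the lower genes these shares were 18.4%, 23.2% and 17.5%. Among the mutants, Delta28 shared 565 higher and 254 lower genes with K>R 1-9 and 560 and 312 with K>R 3, and K>R 1-9 shared 440 and 210 with K>R 3.

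Whether the response itself differed between genotypes was tested as an interaction. The median SE of such a difference was 0.58 on the log2 scale, and a simulated 4-fold difference (log2 of 2) was recovered in 40% of genes for Delta28 against WT. The simulation drew genes independently and changed 200 at once, which eases the adjustment, so 40% may overstate recovery in these data. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 0 genes responded differently in Delta28, K>R 1-9 or K>R 3 than in WT, with 445, 456 and 512 genes at an unadjusted p below 0.05, where 693.7 are expected by chance, and DESeq2 called 0 in each. The same edgeR test called 0 genes for K>R 1-9 against Delta28 (589 unadjusted, DESeq2 1) and 0 for K>R 3 against K>R 1-9 (600 unadjusted, DESeq2 0). Without K>R 3 ABA replicate 2 the last comparison called 1 gene. In every interaction the unadjusted count lay below the expected 693.7, so these tests may be conservative, and 0 calls do not show equal responses. The larger number of genes called in Delta28 (1977) than in WT (798) is thus not a tested difference in response for any single gene.

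Among the 20 lists, 2 had ABA fold changes shifted downward in K>R 1-9 against WT. The list of 4 guard cell markers had a camera adjusted p = 0.00279, and adjusted p = 0.0409 with an estimated correlation (GC1 difference -1.95, SE 0.82; FAMA -1.77, SE 0.71; KAT1 -0.95, SE 0.49; HT1 -0.83, SE 0.95). The same differences from WT were -2.17, -0.53, -0.23 and -1.31 in Delta28 and -2.66, 0.59, 0.52 and -2.14 in K>R 3 for GC1, FAMA, KAT1 and HT1, none of them called by edgeR. This list call was lost without K>R 1-9 mock replicate 3 (camera adjusted p = 0.0648). That library was at -52.3 on the fourth principal component, where the 5 other K>R 1-9 libraries lay between -10.8 and 4.60. The list of 17 salicylate and immune genes was also shifted (camera adjusted p = 0.0301; adjusted p = 0.816 with an estimated correlation). The salicylate synthesis gene ICS1 (AT1G74710) was at -1.20 (SE 0.71) and the transporter EDS5 (AT4G39030) at -1.14 (SE 0.67). No member of the 2 lists was called by edgeR. The salicylate call was lost without WT mock replicate 2, WT ABA replicate 3, K>R 1-9 mock replicate 3 or K>R 1-9 ABA replicate 3 (camera adjusted p up to 0.373). No list differed for Delta28 against WT (lowest adjusted p 0.124), K>R 3 against WT (0.0948) or K>R 3 against K>R 1-9 (0.112) with all libraries. Without Delta28 ABA replicate 1, Delta28 mock replicate 1 or WT ABA replicate 3, 1 list passed for Delta28 against WT, and 2 did without Delta28 mock replicate 2 or WT mock replicate 1. For K>R 3 against WT 3 lists passed without K>R 3 ABA replicate 1, 2 without K>R 3 mock replicate 1 or 3, and 1 without K>R 3 ABA replicate 3 or WT ABA replicate 2 or 3. For K>R 3 against K>R 1-9 2 lists passed without K>R 1-9 ABA replicate 3 or K>R 3 ABA replicate 2 or 3, and 1 without K>R 1-9 mock replicate 1 or 3 or any K>R 3 mock replicate. The lists of PP2C phosphatases, LEA and marker genes and antenna genes passed in none of the comparisons with WT when all libraries were used.

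Between the lines with the 2 larger tail changes, 3 lists responded differently in K>R 1-9 than in Delta28 by camera, and 0 did with an estimated correlation. In mock leaves these lines also differed in HTA11 transcripts (450 CPM in K>R 1-9 and 7.97 CPM in Delta28). Such list differences therefore cannot be assigned to the tail alone. The list of 4 ABA receptors, without its single-exon members, was shifted downward in K>R 1-9 (adjusted p = 0.0252, and adjusted p = 0.0966 with an estimated correlation), with PYL8 at -0.91 (SE 0.35) and PYL1 (AT5G46790) at -0.63 (SE 0.32). So was that of 9 senescence genes (adjusted p = 0.0364, and adjusted p = 0.293 with an estimated correlation), with SAG13 at -1.95 (SE 0.88) and PAO at -0.75 (SE 0.46). The list of 9 SWR1 and INO80 subunits was shifted upward (adjusted p = 0.0364, and adjusted p = 0.107 with an estimated correlation), with ARP6 (AT3G33520), an actin-related subunit of SWR1, at 1.83 (SE 0.66) but MBD9 (AT3G01460) at -0.45 (SE 0.29). No member of the 3 lists was called by edgeR. Leaving out 1 of the 12 libraries ended the receptor call in 3 cases (Delta28 ABA replicate 2, K>R 1-9 mock replicate 3 and ABA replicate 2; adjusted p up to 0.0791). It ended the senescence call in 6 cases (Delta28 mock replicate 1, ABA replicates 1 and 2, K>R 1-9 mock replicates 1 and 3, ABA replicate 2; up to 0.199). The SWR1 and INO80 call ended in 7 cases (Delta28 mock replicate 2, ABA replicates 2 and 3, all 3 K>R 1-9 mock replicates and ABA replicate 2; up to 0.123). In all, 0 lists passed without K>R 1-9 mock replicate 3 or ABA replicate 2, and 5 without Delta28 mock replicate 1.

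Response scores gave the size of the ABA effect over whole gene sets. The 1134 ABA-induced genes rose by 1.64 ± 0.22 log2 units in WT (mean ± SE, n = 3 mock and 3 ABA libraries), by 1.85 ± 0.24 in Delta28 (113% of WT), by 1.71 ± 0.22 in K>R 1-9 (104%) and by 1.59 ± 0.15 in K>R 3 (96.8%). The 1123 repressed genes changed by -1.25 ± 0.22 in WT, -1.47 ± 0.20 in Delta28 (117%), -1.40 ± 0.12 in K>R 1-9 (112%) and -1.44 ± 0.23 in K>R 3 (115%). The differences of the induced response from WT were 0.21 (SE 0.32), 0.07 (SE 0.31) and -0.05 (SE 0.26), with exact permutation p of 0.595, 0.845 and 0.885. Those of the repressed response were -0.21 (SE 0.29), -0.15 (SE 0.25) and -0.19 (SE 0.32), with exact permutation p of 0.5, 0.725 and 0.685. All 6 had a Benjamini-Hochberg adjusted p of 0.885 in this exact permutation test, and each difference was smaller than its standard error. With a gene set chosen from WT alone the induced differences of Delta28 and K>R 1-9 (-0.07 and -0.29) and all 3 repressed ones (0.41, 0.43 and 0.45) turned sign, but such a set favours genes that happened to respond more in WT. Without 1 library the induced difference of Delta28 ranged from 0.00421 to 0.39. Those of K>R 1-9 and K>R 3 changed sign, ranging from -0.15 to 0.36 and from -0.25 to 0.08. All 3 were lowest without WT ABA replicate 3, which left almost no difference for Delta28. The K>R 1-9 difference was highest, at 0.36, without K>R 1-9 mock replicate 1. All 3 repressed differences changed sign without WT ABA replicate 3, to 0.005, 0.09 and 0.04, where the other extremes were -0.43, -0.30 and -0.39.

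**Figure D3:**
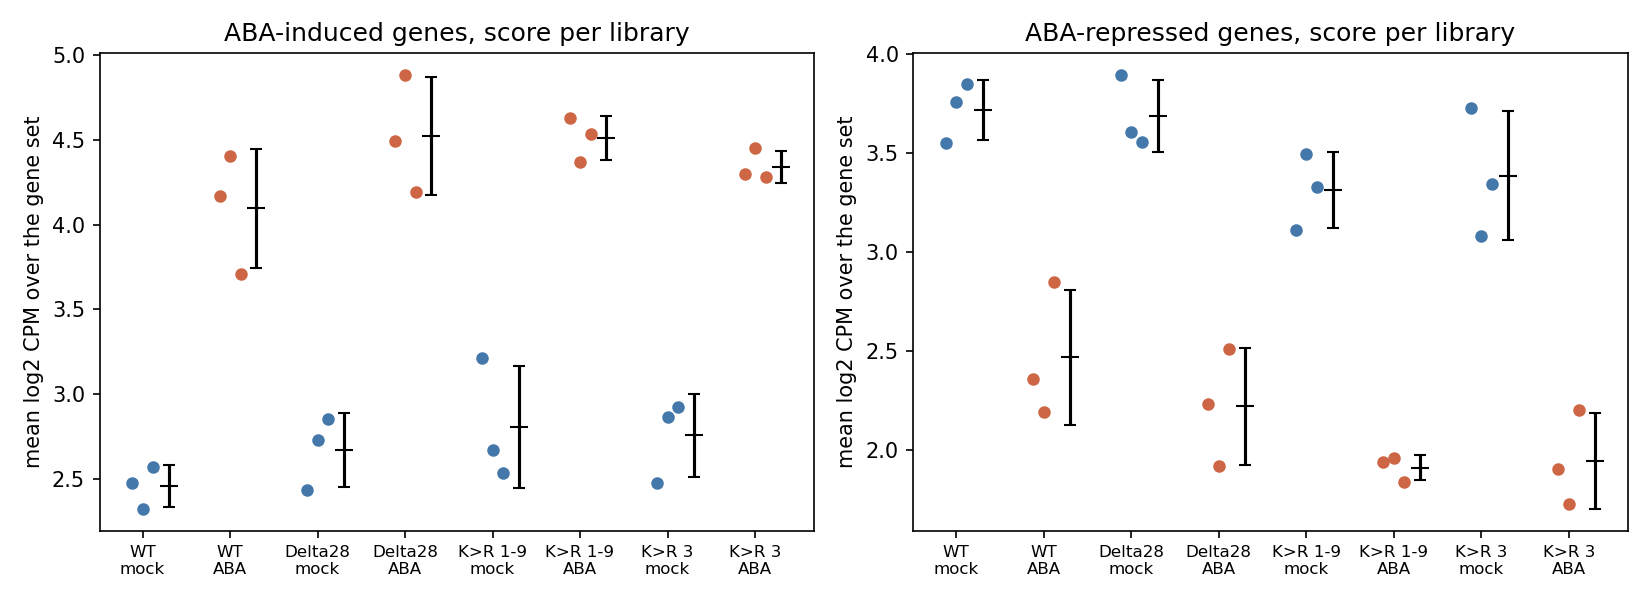
Mean log2 CPM over the 1134 ABA-induced and the 1123 ABA-repressed genes in each library (points), with the mean and SD of 3 libraries per group, for mock and ABA leaves of the 4 genotypes. The induced score was 2.46 in WT mock and 4.52 in Delta28 ABA leaves.

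The level of these gene sets was also compared within each treatment, where 3 against 3 libraries allow no exact permutation p below 0.1. In mock leaves the induced score was higher than in WT by 0.21 in Delta28, 0.35 in K>R 1-9 and 0.30 in K>R 3 (exact permutation p = 0.3, 0.2 and 0.3). The K>R 1-9 value was enlarged by mock replicate 1, which scored 3.21 against 2.67 and 2.53 in the other K>R 1-9 mock libraries. The repressed score differed from WT by -0.03, -0.41 and -0.33 (exact permutation p = 1, 0.1 and 0.2). In ABA leaves the induced differences were 0.43, 0.42 and 0.25 (exact permutation p = 0.2, 0.2 and 0.4) and the repressed ones -0.25, -0.56 and -0.52 (exact permutation p = 0.5, 0.1 and 0.2). WT ABA replicate 3 enlarged all of these differences. Its induced score was 3.71, against 4.17 and 4.41 in the other WT ABA libraries, and its repressed score 2.85, against 2.36 and 2.19.

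Mutant and WT leaves were then compared without ABA, which gives the baseline of each line. In Delta28 the plastid lipoamide dehydrogenase LPD1 (AT3G16950) was higher at 26.3 ± 6.41 against 5.27 ± 0.905 CPM (log2 fold change 2.29, SE 0.43), as were the beta-glucosidase BGLU11 (AT1G02850; 2.07, SE 0.41), the hydrolase AT4G39955 (2.03, SE 0.37), the glutamine synthetase GLN1.3 (AT3G17820; 1.97, SE 0.40) and AT3G25940 (1.63, SE 0.32). The nucleic acid-binding AT2G40960 (-3.39, SE 0.48), the carrier AT1G74240 (-2.74, SE 0.49), HTA9, the membrane-anchored ubiquitin-fold protein MUB2 (AT5G15460; -2.25, SE 0.43) and TON1B (AT3G55005), a protein of the cortical cytoskeleton (-2.13, SE 0.34), were lower. In total 22 genes were called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 6 higher (27.3%) and 16 lower, with 1232 at an unadjusted p below 0.05. DESeq2 called 86, 36 higher (41.9%) and 50 lower. The count was 8, 9 and 4 without WT mock replicates 1, 2 and 3, and 12, 4 and 6 without Delta28 mock replicates 1, 2 and 3. Of the 10 genes named here HTA9 and AT2G40960 passed in all 6 leave-outs. TON1B was lost without Delta28 mock replicate 2 or 3 (adjusted p up to 0.0717) and the others without at least 4 of the 6 libraries, always including Delta28 mock replicate 2 (up to 0.253) in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. That library was at -27.4 and Delta28 ABA replicate 2 at -33.2 on the second principal component, where the 4 other Delta28 libraries lay between 18.8 and 27.4.

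The LEA and marker list was the 1 list to pass in Delta28 mock leaves (camera adjusted p = 0.0274, upward; adjusted p = 0.778 with an estimated correlation), with 0 of 18 genes called over all genes and 1 adjusted over the list alone. RD29B had a log2 fold change of 3.69 (SE 1.00, adjusted p = 0.209 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The list call was lost without WT mock replicate 1 or 3 or Delta28 mock replicate 3 (camera adjusted p up to 0.347). In all, 5 lists passed without Delta28 mock replicate 1 and 2 without WT mock replicate 2. Of 10 flowering genes 0 were called over all genes by edgeR and 3 rose adjusted over the list alone (camera adjusted p = 0.37). Among them the florigen gene FT (AT1G65480) had a log2 fold change of 4.12 (SE 1.13).

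In K>R 1-9 mock leaves CSLG2 (AT4G24000), a cellulose synthase-like enzyme with 3 counts over the WT libraries, had a pooled ratio of 225 (95% interval 76.5 to 1091). AT1G58225 (3.42, SE 0.59), the senescence gene SAG13 (3.21, SE 0.68) and BGLU11 (2.36, SE 0.42) were also higher, besides HTA11. The mevalonate kinase MK (AT5G27450; -2.70, SE 0.48), HTA9, AT1G23750 (-2.38, SE 0.44), MOD1 (AT2G05990), an enoyl reductase of fatty acid synthesis (-2.01, SE 0.32), and the actin ACT3 (AT3G53750; -1.91, SE 0.39) were lower. In total 31 genes were called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 16 higher and 15 lower, with 2006 at an unadjusted p below 0.05, and DESeq2 called 338, 192 higher and 146 lower. The count was 17, 8 and 1 without WT mock replicates 1, 2 and 3, and 10, 42 and 11 without K>R 1-9 mock replicates 1, 2 and 3. HTA9 passed in all 6 leave-outs. The other 9 genes named here were each lost without WT mock replicate 3 and at least 2 further libraries (adjusted p up to 0.198) in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

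Of 16 jasmonate genes 0 were called over all genes by edgeR in K>R 1-9 mock leaves and 11 rose adjusted over the list alone (camera adjusted p = 6.84e-09, upward; adjusted p = 0.427 with an estimated correlation), a list call kept in all 6 leave-outs. VSP2 and VSP1 (AT5G24780), vegetative storage proteins induced by jasmonate, had log2 fold changes of 4.96 and 5.67 (adjusted p = 0.0815 and 0.114 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Salicylate genes were higher as a list (camera adjusted p = 0.018; adjusted p = 0.715 with an estimated correlation), with 0 of 17 called over all genes, 1 adjusted over the list alone and PR5 (AT1G75040) at 3.48. Of 9 senescence genes 1 rose, SAG13, and 2 did adjusted over the list alone (camera adjusted p = 0.039; adjusted p = 0.427 with an estimated correlation). Of 3 epidermis markers 0 were called over all genes and 2 fell adjusted over the list alone (camera adjusted p = 0.043; adjusted p = 0.427 with an estimated correlation), FDH (AT2G26250; -1.11) and PDF2 (AT4G04890; -0.89). The salicylate call was lost without K>R 1-9 mock replicate 3 (camera adjusted p = 0.273), the senescence call without WT mock replicate 1 or K>R 1-9 mock replicate 1 or 3 (up to 0.15) and the epidermis call without WT mock replicate 1 or K>R 1-9 mock replicate 1 or 2 (up to 0.171). In all, 2 lists passed without WT mock replicate 1. FT, at 3.99 ± 1.82 CPM in K>R 1-9 mock leaves, had a pooled ratio of 17.2 (95% interval 6.44 to 64.7). That interval covers counting error alone and leaves out the spread between libraries. The flowering list did not pass (camera adjusted p = 0.107).

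In K>R 3 mock leaves HTA9 was the 1 gene called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with 1794 genes at an unadjusted p below 0.05. DESeq2 called 78, 42 higher (53.8%) and 36 lower. The edgeR count was 13 without K>R 3 mock replicate 1, 2 without K>R 3 mock replicate 3 and 1 in the other leave-outs. Antenna and Rubisco genes were lower as a list (camera adjusted p = 3.22e-11; adjusted p = 0.548 with an estimated correlation), with 0 of 20 called over all genes, 2 adjusted over the list alone, LHCB2.3 at -2.30 and RCA at -1.34. Salicylate genes were higher (camera adjusted p = 2.06e-05; adjusted p = 0.548 with an estimated correlation), with 0 of 17 called by either adjustment, WRKY70 (AT3G56400) at 1.97 and EDS5 at 1.34. Both calls were kept in all 6 leave-outs.

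A further 4 lists passed camera in K>R 3 mock leaves. Jasmonate genes were higher (camera adjusted p = 0.00102; adjusted p = 0.609 with an estimated correlation), with 0 of 16 called by either adjustment and JAZ2 at 2.77. So were the ABA-linked transcription factors (camera adjusted p = 0.0187; adjusted p = 0.609 with an estimated correlation), with 0 of 15 called over all genes, 1 adjusted over the list alone and MYB2 at 2.03. Auxin and expansin genes (camera adjusted p = 0.0269; adjusted p = 0.548 with an estimated correlation; EXPA11, AT1G20190, at -3.11) and vascular markers (camera adjusted p = 0.0162; adjusted p = 0.447 with an estimated correlation; the xylem protease XCP1, AT4G35350, at -1.83) were lower. In each, 0 genes were called over all genes and 1 adjusted over the list alone. The jasmonate call was lost without WT mock replicate 3 or K>R 3 mock replicate 3 (camera adjusted p up to 0.121), the transcription factor call without WT mock replicate 1 (0.114), the auxin call in 5 of 6 leave-outs (up to 0.213, kept without WT mock replicate 2) and the vascular call without K>R 3 mock replicate 2 (0.0712).

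The mutants' baseline changes overlapped in few genes. Delta28 and K>R 1-9 shared BGLU11 and AT4G39955 among the higher genes and HTA9 among the lower, against 0.00692 and 0.0173 genes for independent lists. In 20 simulations of unchanged groups that shared simulated WT libraries the overlap was 0. Unchanged groups give hardly any called genes to share, so these simulations are no reference for the overlap. Each of them shared HTA9 alone with K>R 3. The covariance of log2 fold changes over all genes was 0.358 for Delta28 with K>R 1-9, 0.288 for Delta28 with K>R 3 and 0.389 for K>R 1-9 with K>R 3, against 0.202, 0.202 and 0.203 from the shared WT libraries in the simulations. These exceed the simulations by 0.156, 0.0858 and 0.186, where the SD over the 20 simulations was 0.00637, 0.00586 and 0.00571. The simulations drew each gene independently, so this SD leaves out deviations that many genes of a library share. The excess therefore cannot be judged against it. The correlations were 0.492, 0.442 and 0.497 (simulated 0.534, 0.528 and 0.522), and a correlation also falls as the variance of the fold changes rises. The 3 WT mock libraries cannot be split into parts of at least 2, so part or all of the excess may come from the shared controls.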

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

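Of the tests below, those of the library's place between groups, of mixed RNA, of 1 WT library, of a larger response in Delta28, of the size of the guard cell difference, of the guard cell share and of other splits of the samples were chosen after the results were seen, and those of depth and of 1 library behind the guard cell call after the data but before their own results were seen.

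Lists whose ABA response differed between genotypes by the test of the difference itself were picked out for a closer look. In K>R 1-9 against WT these were the guard cell markers (camera adjusted p = 0.00279, and 0.0409 with an estimated correlation) and the salicylate and immune genes (camera adjusted p = 0.0301, and 0.816 with an estimated correlation), both with fold changes shifted downward in K>R 1-9. In K>R 1-9 against Delta28 they were the ABA receptors (camera adjusted p = 0.0252, shifted lower in K>R 1-9), the senescence genes (camera adjusted p = 0.0364, lower) and the SWR1 and INO80 subunits (camera adjusted p = 0.0364, higher). None of these 3 lists passed with an estimated correlation (camera adjusted p = 0.0966, 0.293 and 0.107).

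The list of guard cell markers GC1, FAMA, KAT1 and HT1 was shifted downward in K>R 1-9 against WT, with a median difference of -1.36 log2 units (SE 0.49 to 0.95), although edgeR called none of the 4, nor in Delta28 against WT (GC1 -2.17, FAMA -0.53, KAT1 -0.23 and HT1 -1.31, SE 0.49 to 0.96) or K>R 3 against WT (GC1 -2.66, FAMA 0.59, KAT1 0.52 and HT1 -2.14, SE 0.49 to 1.00). The call ended without K>R 1-9 mock replicate 3, where camera gave an adjusted p of 0.0648 (0.000463 to 0.0378 without each of the 11 others) and the median was -1.19 (SE 0.53 to 0.98), and it held at -1.07 without WT ABA replicate 1. The difference of the mean over the markers was -1.27 (SE 0.51, 95% interval -2.44 to -0.106) with all libraries. It was nearest to 0, at -0.97 (SE 0.46, 95% interval -2.055 to 0.117), without K>R 1-9 mock replicate 3. The interval also included 0 without WT mock replicate 2, WT ABA replicate 1 or 3, or K>R 1-9 mock or ABA replicate 2. It excluded 0 without each of the other libraries. Whether 1 library also makes the size of the difference is therefore not decided. HT1 and FAMA were low, with means of 2.36 and 4.05 CPM. A smaller share of guard cells in ABA-treated K>R 1-9 leaves would lower all 4 markers alike, and their differences spanned 1.12 log2 units, a studentized range of 1.47 against a critical value of 4.05, so this and a change within guard cells cannot be told apart with 4 markers. A biological difference between the genotypes stays open as untested beyond this.

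The level of HTA11 in K>R 3 mock replicate 2, 789 CPM, lay within the range of K>R 1-9 and above the 5 other K>R 3 libraries. A K>R 1-9 library under the wrong label is argued against: on an axis of 100 genes from K>R 3 (0) to K>R 1-9 (1) it lay at 0.0521, where the 6 K>R 1-9 libraries lay at 0.568 to 0.893 and the other K>R 3 libraries at 0.141 to 0.963 (0.963 in K>R 3 ABA replicate 3). Mixed mock K>R 1-9 RNA is argued against too, as even the mock K>R 1-9 library highest in HTA11 (491 CPM) would have to make up 161% of it. RNA of the highest ABA-treated K>R 1-9 library would have to make up 78.3%, which would place it at 0.618 or more between K>R 3 mock (0) and K>R 1-9 ABA (1), and it lay at 0.114, the K>R 1-9 ABA libraries being at 0.790 to 0.897. No biological explanation was tested.

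More genes were called for ABA in Delta28 (1977) than in WT (798). A difference in depth is argued against: with every library thinned to the smallest total, Delta28 had 1462 calls and WT 686, a ratio of 2.13 against 2.48 before thinning. A single weakly responding WT library was examined by leaving out WT ABA replicate 3, which gave 809 calls in WT, against 1147, 991 and 1943 in Delta28 without ABA replicates 1, 2 and 3. This lies under all 3, but under the lowest by less than the WT counts moved with the library left out (382 and 240 without ABA replicates 1 and 2), so it does not decide. A larger ABA response in Delta28 also stays open, as the induced score was higher than in WT by only 0.21 (exact permutation p = 0.595). Without WT ABA replicate 3 that difference was 0.00421.

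Other splits of the same 6 samples into 3 and 3 were counted for each comparison of a pair of groups. There are 10 such splits, too few for a share under 0.05. For ABA the real split called 798 genes in WT against at most 0 in the others, 1977 against 0 in Delta28, 1292 against 6 in K>R 1-9 and 1496 against 1 in K>R 3. For the mock comparisons it called 22 against 0 in Delta28, 31 against 0 in K>R 1-9 and 1 against 0 in K>R 3. In each of these 7 comparisons 1 of the 10 splits, the real one, called as many genes. For the 5 interactions, where the real count was 0, all 40 of 40 splits called as many, as any count is at least 0, so these splits say nothing about chance. The highest other split called 2 genes for Delta28 against WT, 23 for K>R 1-9 against WT, 0 for K>R 3 against WT, 3 for K>R 1-9 against Delta28 and 1 for K>R 3 against K>R 1-9. The split with 23 calls may point to a structure of the samples, which was not tested.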

How the results depend on the processing

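Chosen after the data were seen were plus-strand genes alone, the joint removal of WT mock replicate 2 and K>R 3 mock replicate 2 (joint removal), and the list alternatives except the estimated correlation. No call count moved by over 1.5 times with RLE scaling, with no filter or with a 2-fold minimum. DESeq2 called 1277 genes for ABA in WT, 86, 338 and 78 in mock Delta28, K>R 1-9 and K>R 3 against WT, and 1 for the interaction of K>R 1-9 with Delta28. Joint removal gave 255 for ABA in WT and 9 and 7 in mock Delta28 and K>R 1-9, which comes with fewer libraries. Plus-strand genes alone gave 34 in mock Delta28. Fitting only the groups compared gave 430 for ABA in K>R 3 and 10 in mock K>R 1-9, where a stricter filter gave 57. The cause was not tested for DESeq2, the strand, the fit and the filter. Without 1 library the ABA counts ranged over 240 to 809 in WT, 888 to 1943 in Delta28, 532 to 1327 in K>R 1-9 and 529 to 1390 in K>R 3, and the mock counts over 4 to 12, 1 to 42 and 1 to 13. The interaction of K>R 3 with K>R 1-9 ranged over 0 to 1, and the other 4 interactions stayed at 0. The induced score differences from WT turned sign with the gene set from WT alone in Delta28 (-0.0714, exact permutation p = 0.85) and K>R 1-9 (-0.29, p = 0.515), with a mean CPM of at least 10 in K>R 1-9 (-0.00664, p = 0.98), and in K>R 3 with the gene set from the mutants (0.0741, p = 0.82), no fold minimum (0.000275, p = 0.99) and joint removal (0.0875, p = 0.683). The repressed ones turned with the gene set from WT alone in all 3 mutants (0.41, 0.43 and 0.45, exact permutation p = 0.18, 0.22 and 0.3). A set chosen in WT alone favours genes that happened to respond more there. Without 1 library the induced differences ranged from 0.00421 to 0.39, -0.15 to 0.36 and -0.25 to 0.0781 and the repressed ones from -0.43 to 0.00470, -0.30 to 0.0867 and -0.39 to 0.0378. With an estimated correlation 3, 1, 4 and 1 lists passed for ABA in WT, Delta28, K>R 1-9 and K>R 3, 1 for K>R 1-9 with WT, 0 for K>R 1-9 with Delta28 and 0 in each mock comparison. Joint removal gave 1 list for K>R 1-9 with WT, 1 for K>R 3 with K>R 1-9, 2 in mock Delta28 and 1 in mock K>R 1-9. Plus-strand genes gave 0 for K>R 1-9 with WT, where too few guard cell markers were left for a test, 0 for K>R 1-9 with Delta28, and 0, 2 and 3 in the mock comparisons. Without 1 library the lists passed ranged over 0 to 2 (Delta28 with WT), 1 to 3 (K>R 1-9 with WT), 0 to 3 (K>R 3 with WT), 0 to 5 (K>R 1-9 with Delta28), 0 to 2 (K>R 3 with K>R 1-9), 0 to 5 (mock Delta28) and 2 to 5 (mock K>R 1-9). The replicate numbers showed no pairing of the libraries over all groups together. Over 84 pairs of the same number the correlation of deviations ran from -0.238 to 0.274 (median -0.008). Of these, 16 pairs exceeded 0.1, and 10 of 24 libraries correlated best with their own number. Mock and ABA libraries of the same number within a genotype were not examined apart. With a replicate block 725, 1914, 1229 and 1464 genes were called for ABA and 16, 27 and 1 in mock leaves, no count of calls moving by over 1.5 times, and the jasmonate list passed in Delta28 (camera adjusted p = 0.0463). Of the values of the genes named in the report, 11 of 175 lost their call with a replicate block, 2 with RLE scaling, 2 with no filter, 26 of 172 when only the groups compared were fitted and 32 with joint removal. DESeq2 added 8 calls among 170 and ended 0, plus-strand genes alone (113) and the stricter filter (169) ended 0, and 0 changed sign in any of these settings. WT mock replicate 2, with 1565518 counts, has the highest detection floor, and simulated differences in response of log2 size 1 and 2 were recovered in 0% and 40% of genes, which may overstate recovery in the real data.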

Other observations

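The gene groups and tests described here were all chosen after the data were seen. Further groups were examined in the mean ABA effect over the 4 genotypes, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of 25 autophagy genes, which recycle cell contents, 18 rose and 0 fell (camera adjusted p = 6.71e-08, and adjusted p = 0.0746 with an estimated correlation). APG8A (AT4G21980), a protein of the autophagosome membrane, changed by 1.96 on the log2 scale (SE 0.15), APG7 (AT5G45900) by 1.54 (SE 0.19) and ATG8E (AT2G45170) by 1.48 (SE 0.20). Of 7 genes of branched-chain amino acid and lysine breakdown 4 rose (camera adjusted p = 0.00554, and adjusted p = 0.0746 with an estimated correlation), among them AT4G33150 (5.28, SE 0.46) and IVD (AT3G45300; 1.18, SE 0.15); over plus-strand genes alone this list did not pass (camera adjusted p = 0.206).

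Of 48 genes annotated as cytosolic ribosomal proteins or their families 37 fell and 1 rose, AT3G01170 (0.27, SE 0.11), which was not called with RLE scaling (camera adjusted p = 1.42e-08, and adjusted p = 0.17 with an estimated correlation). Of 15 aquaporins 4 rose and 2 fell (camera adjusted p = 0.622), and of 14 xyloglucan endotransglucosylases, which loosen cell walls, 4 rose and 4 fell (camera adjusted p = 0.858). Among the latter XTH6 (AT5G65730) changed by -2.29 (SE 0.38) and XTH30 (AT1G32170) by 1.55 (SE 0.29).

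A hypothesis is that the mutants share a shift of ABA-responsive genes toward the ABA-treated state, apart from the size of the response. In mock leaves the induced score was higher in the 9 mutant than in the 3 WT libraries by 0.29 (exact permutation p = 0.0909, 220 arrangements) and the repressed score differed by -0.26 (exact permutation p = 0.168), which does not decide. In Delta28 alone the repressed score of mock leaves differed by only -0.03 (SE 0.14, exact permutation p = 1). Over both treatments, with 18 mutant and 6 WT libraries, the differences were 0.33 (SE 0.12, exact permutation p = 0.00715, 48400 arrangements) and -0.35 (SE 0.12, exact permutation p = 0.00862). This does not decide either, as the hypothesis came from these same libraries and WT is 1 line against 3: over the 4 genotypes the exact permutation p was 0.25 for both, the smallest possible. As the labels give all 3 mutants the same H2A.Z null background, which the remaining HTA9 transcripts cannot check, a shift common to them may come from that background, from the tail changes or from growth differences, and the 2 scores are not independent of each other.

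K>R 3 ABA replicate 3 stood apart from its genotype. On the second principal component it was at 31.1, where the 5 other K>R 3 libraries lay between -53.9 and -32.5 and the K>R 1-9 libraries between -0.224 and 45.9. On the axis from K>R 3 (0) to K>R 1-9 (1) it was at 0.963, above the 6 K>R 1-9 libraries (0.568 to 0.893). Its HTA11 level was 22.1 CPM, against 420 to 1008 CPM in the K>R 1-9 libraries. Without it 1160 genes were called for ABA in K>R 3 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, against 1496 with all libraries. K>R 1-9 mock replicate 3, at -52.3 on the fourth component against -10.8 to 4.60 in the 5 other K>R 1-9 libraries, also stood apart, and the guard cell, salicylate, receptor, senescence and SWR1 and INO80 list calls in K>R 1-9 all ended without it. For the guard cell list the median difference was -1.19 without it and -1.36 with all libraries, and -1.07 without WT ABA replicate 1, where the call held, so the lost call does not show that this library makes the shift. In Delta28, mock replicate 2 (-27.4) and ABA replicate 2 (-33.2) lay apart from the 4 other libraries (18.8 to 27.4) on the second component. The 3 list calls of K>R 1-9 against Delta28 ended without Delta28 ABA replicate 2, and the SWR1 and INO80 call also without Delta28 mock replicate 2. WT ABA replicate 3 was at -2.33 on the first component, where the other ABA libraries lay between 28.7 and 70.5. Without it the induced and repressed score differences of Delta28 from WT were 0.00421 and 0.00470, against 0.21 and -0.21 with all libraries.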
